A study of Rattus norvegicus with 287 samples.

How the data were processed

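RNA was measured by sequencing in tissues of rats treated with focused ultrasound or sham, 287 libraries in 70 groups and 8 tissues. Per the labels, ultrasound was given at 1.1 MHz for 3 minutes a day (200 mV per pulse, 150 burst cycles, burst period 500 µs), and libraries were made with a stranded mRNA kit, or a stranded total RNA kit for pancreas and adipose tissue. Reads were aligned with STAR 2.5.3a and quantified with RSEM on Rnor_6.0, per the submitters' processing notes, and the annotation release is not given in the sources used here. The deposited values are expected counts per gene, present as whole numbers, so rounded, and not normalized. Counts per isoform, also deposited, were not used. Of the 32623 genes, 7769 had a total of 0. Symbols found in the RefSeq gene list numbered 19062, and genes named only by an Rfam family were treated as not nameable.

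Total counts ran from 5754208 to 17540932 in adipose tissue, 14542715 to 36498514 in blood, 6946906 to 16504326 in brain, 9411372 to 19041490 in intestine, 8196905 to 20784994 in kidney, 6507872 to 43088790 in liver, 6027440 to 22125416 in muscle and 2380545 to 22986066 in pancreas. No library was left out of the counts reported first. Sex and tissue labels were checked with Y-linked and tissue marker genes. Of 477 pairs of libraries within groups 0 were identical, and the lowest chi-square per degree of freedom was 2.97. Non-polyadenylated RNAs were 4045 genes by type or family.

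Each tissue was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group at a minimum count of 10, and quasi-likelihood F tests with robust dispersions. Adjusted p is the Benjamini-Hochberg value over genes tested, with a threshold of 0.05, and SE is the absolute log2 fold change over the square root of F. Groups of a cohort shared a fit, the difference between effects was tested as an interaction, and fits of DIO rats held a sex term. The 11 comparisons gave 51 counts over tissues, with diet resistant rats compared in liver and pancreas. Lists of genes, 35 in all with at least 5 members tested, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. Signed clock genes of lean liver were compared by exact permutation of the libraries, and relations of clock scores by permutation. Scores and correlations used log2 CPM with a pseudocount of 1.

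Comparisons, lists, thresholds, the rule for named genes and the first alternatives were set before the data were examined. By that rule the text names, among genes past the threshold with a usable symbol, a mean CPM of at least 5 in one group and no overlap of libraries (not asked of the interaction or with a sex term), the 3 with the largest rise and fall for obese against lean controls and for obese pFUS against control, and the 2 for others. It may also name up to 4 members of a list in a tissue, the largest changes first, and markers for sex and tissue. Not every gene it allows is named. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, only the 2 groups compared, male libraries only, no sex term and leaving out each library. Fits without doubted libraries or without non-polyadenylated RNAs were added after seeing the data. Other splits of the libraries were counted, at most 100 drawn with a fixed seed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, data.table (version 1.17.8) and matplotlib 3.10.9 were used.

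Every comparison was tried on simulated counts, with 100 genes changed per fold size. Of genes changed 2-fold and 4-fold, 55% and 95% were recovered for obese against lean liver, 43% and 99% for obese liver with pFUS, 3% and 42% for obese adipose tissue with pFUS, 0% and 3% for the difference between effects there, 94% and 97% for 3-day x1 liver and 16% and 85% for DIO-stz liver. These rates are for the genes changed and may not hold at low counts. In simulations without correlation, 51 of 51 changed lists were called and 20 of 1020 unchanged had p under 0.05. No real call held with an estimated one.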

Results

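The libraries come from rats given peripheral focused ultrasound (pFUS) aimed at the porta hepatis, or a sham treatment, for 3 days, 4 weeks or 7 weeks. They are 55 of liver, 52 of muscle, 48 of adipose tissue, 31 of blood, 31 of brain (hypothalamus in the design text), 29 of intestine, 21 of kidney and 20 of pancreas. Obese Zucker Diabetic Fatty (ZDF) rats at 7 weeks were 5 controls and 5 with pFUS (4 and 4 for adipose tissue). Lean Zucker groups held 4 or 5 rats (3 for intestine with pFUS) and no kidney or pancreas. The 3-day and 4-week groups were 4 obese ZDF rats each, with liver, adipose tissue and muscle. DIO-stz controls were 2 females and 2 males, and DIO-stz pFUS groups 3 to 5 rats with at most 1 female. Total counts ran from 2380545 to 43088790, with a median of 12849617. Replicates are different animals, and a number in a cohort is taken from the labels to mark the same animal in every tissue, so p-values measure variation between rats and tissues of the same rats are not independent.

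Values in brackets after a gene are its log2 fold change ± standard error (SE) from edgeR. After a list they are the members that rose, fell and did not pass, those passing upward and downward when adjusted over the list alone, and the list test. After a gene losing the threshold when 1 library is left out they are the refits where it did and the highest adjusted p. Levels are library-size scaled counts (CPM), mean ± SD, and those of Ucp1, Fabp6 and Havcr1 in single libraries were chosen after their values were seen. No list call held with an estimated correlation: 0 of 55 list tests for obese against lean controls (30 at the preset correlation, 21 upward and 9 downward), 0 of 72 for pFUS in obese rats (29, 10 and 19), 0 of 55 in lean rats (28, 11 and 17), 0 of 30 each for 3-day x1 (7, 1 and 6) and x10 (11, 4 and 7), and 0 of 72 in DIO-stz rats (23, 10 and 13). The median log2 fold change opposed the call in 1 of the 30 and 1 of the 29.

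Y-linked Kdm5d and Eif2s3y together reached at least 1.37 CPM in 249 male libraries and at most 0.137 CPM in 38 female ones. Alb of hepatocytes lay between 63305 and 211173 CPM in liver and at most at 1538 CPM elsewhere. Adipose tissue departed from its label. Ckm, the creatine kinase of striated muscle, was at 21792 CPM in the library labelled lean control adipose 12, at 17282, 18785 and 18076 CPM in those labelled lean pFUS adipose 17, 18 and 19, and at 16510.3 CPM in that labelled obese pFUS adipose 6. These 5 held at most 15.6 CPM of the adipocyte hormone Adipoq, against a median of 4228 CPM over libraries labelled adipose. Umod, a kidney protein, was at 474 and 172 CPM in those labelled lean control adipose 11 and lean pFUS adipose 16. Ucp1, the uncoupling protein of brown fat, was at 751, 572 and 1184 CPM in obese control adipose 4 and 5 and obese pFUS adipose 9, the last with 2579.9 CPM of Ckm. Gene ENSRNOG00000030106, chosen after its values were seen, departs from the numbers of animals. In obese pFUS 8 it was at 2.52 CPM or more in brain, kidney, liver and pancreas and at most 1.80 CPM in blood, intestine and muscle, and in obese pFUS 9 at most 0.251 CPM and at least 4.74 CPM. In obese control 5 it was at 7.86 and 47.7 CPM in blood and intestine and at most 0.738 CPM in the other 5 tissues apart from adipose.

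**Figure D1:**
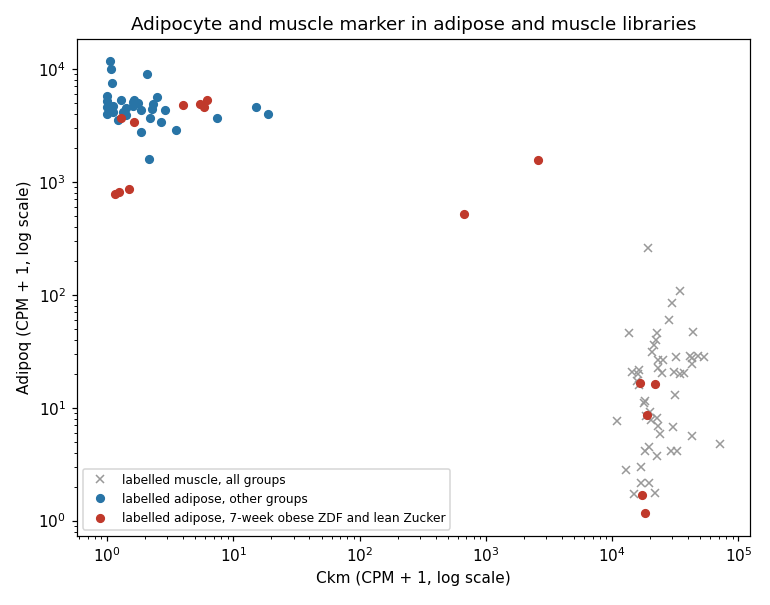
Adipoq against Ckm (CPM + 1, log axes), 1 point per library, for libraries labelled adipose (7-week obese and lean groups red, other groups blue) and muscle (grey crosses). Of the red points, 5 lie among the muscle libraries.

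Obese and lean controls at 7 weeks differed in liver at 1798 of 12585 genes (n = 5 and 5), 1024 higher and 774 lower in obese rats. De novo lipogenesis genes tested upward (9 rose, 0 fell, 12 did not, 10 and 0 adjusted over the list alone, up, adjusted p = 4.60e-06, adjusted p = 0.423 with an estimated correlation), with Pnpla3 (ENSRNOG00000022268, 5.77 ± 0.95), Elovl6 (ENSRNOG00000010468, 4.93 ± 0.86), Scd (ENSRNOG00000013552, 3.76 ± 0.49) and Gpam (ENSRNOG00000015124, 2.97 ± 0.37), for a lipid droplet protein, a fatty acid elongase, a desaturase and the acyltransferase that begins glycerolipid synthesis. The lipase relative Pnpla5 (ENSRNOG00000022296, 9.56 ± 1.26) rose too. Fatty acid oxidation genes tested upward (13 rose, 0 fell, 16 did not, 14 and 0 adjusted over the list alone, up, adjusted p = 9.37e-09, adjusted p = 0.200 with an estimated correlation), with Pdk4 (ENSRNOG00000009565, 3.36 ± 0.39), Fgf21 (ENSRNOG00000020990, 3.28 ± 0.51) and Plin2 (ENSRNOG00000007060, 3.02 ± 0.27), for an inhibitor of pyruvate dehydrogenase, a hormone and a lipid droplet coat. Cyp7a1 (ENSRNOG00000009488, -2.77 ± 0.59) and Abcg8 (ENSRNOG00000005420, -4.20 ± 0.65) fell, for a bile acid synthesis enzyme and a sterol exporter subunit. Inflammatory genes tested upward (8 rose, 0 fell, 14 did not, 11 and 0 adjusted over the list alone, up, adjusted p = 4.25e-05, adjusted p = 0.200 with an estimated correlation), with Lcn2 (ENSRNOG00000013973, 5.92 ± 0.51), and macrophage markers tested upward too (8 rose, 0 fell, 11 did not, 15 and 1 adjusted over the list alone, up, adjusted p = 4.49e-06, adjusted p = 0.535 with an estimated correlation). Ubd (ENSRNOG00000000768, -7.46 ± 0.50, 0.0741 ± 0.0747 against 15.7 ± 3.77 CPM), a ubiquitin-like protein induced by cytokines, fell. Its obese 3-day and 4-week values overlapped lean ones. Of clock genes (4 rose, 8 fell, 6 did not, 5 and 10 adjusted over the list alone, down, adjusted p = 0.0509, adjusted p = 0.443 with an estimated correlation), the activators Arntl (ENSRNOG00000014448, 4.86 ± 0.44) and Npas2 (ENSRNOG00000013408, 4.05 ± 0.40) were higher and Ciart (ENSRNOG00000042717, -6.11 ± 0.68) and Dbp (ENSRNOG00000021027, -4.15 ± 0.45) lower. The sulfotransferase gene Sult4a1 (ENSRNOG00000046975) had no counts in lean control liver, so its rise is at least 8.41 on the log2 scale against 3 counts over the group. Without lean control 15 and obese pFUS 7, far from their groups, the count was 2340 (n = 5 and 4). Genes named had adjusted p from 4.88e-10 to 0.00301. Groups overlapped for Pnpla3.

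In muscle 6610 of 12577 genes differed (n = 5 and 4), 3397 higher and 3213 lower in obese controls. Selenow (ENSRNOG00000013548, 9.04 ± 1.13), Angptl4 (ENSRNOG00000007545, 7.26 ± 0.54) and Myl3 (ENSRNOG00000020955, 6.10 ± 1.52) rose most by the rule for named genes, for a selenoprotein, a lipoprotein lipase inhibitor and a slow fibre myosin light chain. Fatty acid oxidation genes tested upward (20 rose, 2 fell, 3 did not, 20 and 2 adjusted over the list alone, up, adjusted p = 4.25e-05, adjusted p = 0.584 with an estimated correlation), with Ucp3 (ENSRNOG00000017716, 4.21 ± 0.43) and Pdk4 (3.86 ± 0.46), as did slow fibre genes (10 rose, 0 fell, 3 did not, 10 and 0 adjusted over the list alone, up, adjusted p = 0.00423, adjusted p = 0.624 with an estimated correlation). Adipocyte markers tested upward (12 rose, 0 fell, 5 did not, 13 and 0 adjusted over the list alone, up, adjusted p = 2.42e-04, adjusted p = 0.423 with an estimated correlation), with Lep (ENSRNOG00000045797, 5.96 ± 1.13) and Adipoq (ENSRNOG00000001821, 2.82 ± 0.65). The insulin receptor substrate Irs1 (ENSRNOG00000014597, -3.67 ± 0.38) fell, and the clock list tested downward (4 rose, 10 fell, 5 did not, 5 and 11 adjusted over the list alone, down, adjusted p = 0.0260, adjusted p = 0.400 with an estimated correlation). The largest falls, Rpph1 (ENSRNOG00000054493, -12.28 ± 0.50) and Rn7sl1 (ENSRNOG00000061096, -11.41 ± 0.73), were RNAs without a poly(A) tail, of RNase P and the signal recognition particle. Such RNAs took 0.00232% to 0.0205% of counts in obese 7-week muscle and 4.02% to 9.29% in lean muscle. Without them the count was 6508, which cannot part obesity from library kind for genes above. Genes named had adjusted p from 2.74e-12 to 0.00367. Groups overlapped for Adipoq.

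**Figure D2:**
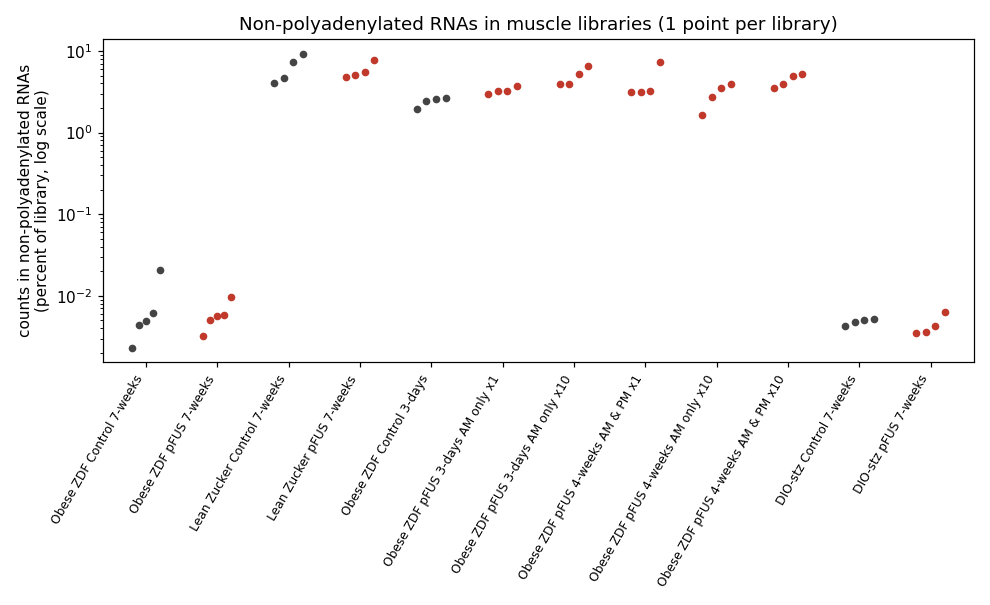
Percentage of counts in non-polyadenylated RNAs in muscle (log axis), 1 point per library, controls dark grey and pFUS red. Obese 7-week and DIO-stz libraries lie at 0.0205% or below, and lean 7-week, 3-day and 4-week libraries at 1.63% or above.

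In blood 297 of 9400 genes differed (n = 5 and 5), 220 higher and 77 lower in obese controls. Neutrophil genes tested upward (3 rose, 0 fell, 10 did not, 8 and 0 adjusted over the list alone, up, adjusted p = 1.05e-04, adjusted p = 0.535 with an estimated correlation), with Lcn2 (6.07 ± 1.24) and Camp (ENSRNOG00000020733, 1.67 ± 0.41). Lymphocyte genes tested downward (0 rose, 3 fell, 21 did not, 1 and 11 adjusted over the list alone, down, adjusted p = 3.30e-05, adjusted p = 0.535 with an estimated correlation), with the B cell gene Fcrla (ENSRNOG00000003136, -0.84 ± 0.21). The antiviral gene Ifit1 (ENSRNOG00000019050, 6.33 ± 0.96) rose in the interferon list (1 rose, 0 fell, 24 did not, 2 and 0 adjusted over the list alone, up, adjusted p = 0.00106, adjusted p = 0.614 with an estimated correlation). By the rule Fbln1 (ENSRNOG00000014137, 5.39 ± 1.00) and Xpo7 (ENSRNOG00000013288, 3.78 ± 0.56) rose, a matrix protein and a nuclear exporter. Without lean control 12 and lean pFUS 18, far from their groups, the count was 709 (n = 5 and 4). Without 1 library, the blood count was 69 (lean 15), 76 (obese 4), 105 (lean 14), 127 (lean 13), 157 (obese 2), 179 (obese 3), 184 (lean 11), 569 (obese 5). Blood genes losing the threshold without 1 library were Camp (4 of 10, 0.0940 without obese 2), Fcrla (6 of 10, 0.103 without lean 15), Lcn2 (1 of 10, 0.0588 without lean 15). For the genes named, adjusted p ran from 0.00371 to 0.0288. Overlap between groups was present for Camp, Fcrla and Ifit1.

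In brain 50 of 14791 genes differed (n = 5 and 5), 21 higher and 29 lower in obese controls. Syngr3 (ENSRNOG00000012620, 1.87 ± 0.24), C3 (ENSRNOG00000046834, 1.52 ± 0.31) and Lcn2 (3.20 ± 0.52) rose, a synaptic vesicle protein, complement component 3 and lipocalin 2. Egfl8 (ENSRNOG00000000436, -1.60 ± 0.32) and Npas4 (ENSRNOG00000020009, -2.55 ± 0.46) fell, the latter an activity-induced transcription factor. Oligodendrocyte genes tested downward (0 rose, 0 fell, 14 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 1.42e-04, adjusted p = 0.584 with an estimated correlation) and those of choroid plexus and pituitary, which border the hypothalamus, upward (0 rose, 0 fell, 10 did not, 0 and 0 adjusted over the list alone, up, adjusted p = 0.0303, adjusted p = 0.621 with an estimated correlation). Without lean control 11 and lean pFUS 19, far from their groups, the count was 114 (n = 5 and 4). The brain count without 1 library was 24 (obese 2 or obese 3), 26 (lean 15), 27 (lean 13), 30 (lean 12), 31 (lean 14), 33 (obese 1). In brain the threshold was missed without 1 library by C3 (8 of 10, 0.126 without lean 14), Egfl8 (9 of 10, 0.101 without obese 5), Npas4 (1 of 10, 0.0597 without obese 3). Over the genes named, adjusted p ran from 8.70e-04 to 0.0359. Libraries of the groups overlapped for Npas4.

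In intestine 2 of 14709 genes passed (n = 5 and 5): Ifit1 (10.69 ± 1.31) was higher in obese controls and Gcnt3 (ENSRNOG00000059540, -0.91 ± 0.12), a mucin glycosyltransferase, lower. Goblet and Paneth cell genes tested downward (0 rose, 0 fell, 13 did not, 0 and 10 adjusted over the list alone, down, adjusted p = 1.40e-07, adjusted p = 0.367 with an estimated correlation). The ileal gene Fabp6 was at 5687 CPM in obese control 1, 8719.5 and 14139.9 CPM in lean controls 11 and 14, and at most 4.25 CPM in the other 7. Without these 3 edgeR called 0 (n = 4 and 3, 1839 at an unadjusted p under 0.05, and 142 with DESeq2 with them). Leaving 1 library out, intestine gave 8 (obese 1), 17 (lean 14), 27 (obese 5), 187 (lean 15). In adipose tissue 4 of 13736 genes passed (n = 4 and 4), all lower in obese controls: Esr1 (ENSRNOG00000019358, -2.87 ± 0.35), Tst (ENSRNOG00000000186, -2.42 ± 0.35) and Dbp (-2.26 ± 0.34), for oestrogen receptor alpha, a sulfurtransferase and a clock output factor, and Gstk1 (ENSRNOG00000016484, -1.37 ± 0.18, adjusted p = 0.0140), chosen after its values were seen. Fast fibre genes tested downward (0 rose, 0 fell, 14 did not, 0 and 13 adjusted over the list alone, down, adjusted p = 4.25e-05, adjusted p = 0.584 with an estimated correlation), with lean control 12 holding muscle genes. Without libraries holding muscle or kidney genes the adipose count was 36 (n = 4 and 2), and without brown fat ones too 2067 (n = 2 and 2). Refits of adipose lacking 1 library called 0 (obese 1, obese 2 or obese 4), 1 (obese 5), 2 (lean 12). Adipose genes losing the threshold without 1 library were Esr1 (3 of 8, 0.0900 without obese 4), Tst (5 of 8, 0.157 without obese 5), Dbp (6 of 8, 0.189 without obese 5), Gstk1 (4 of 8, 0.105 without obese 2). Adjusted p for the genes named ran from 1.98e-04 to 0.0281. The groups overlapped for Ifit1.

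With pFUS for 7 weeks, liver of obese rats had 50 of 12585 genes past the threshold (n = 5 and 5), 6 higher and 44 lower. The clock genes Ciart (3.71 ± 0.68), Dbp (2.93 ± 0.43) and Per3 (ENSRNOG00000018413, 2.25 ± 0.46) rose and the activator Arntl (-2.58 ± 0.38, 4.76 ± 1.55 against 26.6 ± 6.79 CPM) fell, in a list that did not pass as a whole (4 rose, 3 fell, 11 did not, 8 and 5 adjusted over the list alone, up, adjusted p = 0.0518, adjusted p = 0.510 with an estimated correlation). Pdk4 (-2.91 ± 0.38) and Irs2 (ENSRNOG00000023509, -2.42 ± 0.50) fell, for metabolic regulators, with the stress-induced Atf3 (ENSRNOG00000003745, -2.84 ± 0.51) and Gdf15 (ENSRNOG00000019661, -2.63 ± 0.45). Inflammatory genes tested downward (0 rose, 1 fell, 21 did not, 0 and 2 adjusted over the list alone, down, adjusted p = 0.00205, adjusted p = 0.494 with an estimated correlation), as did macrophage markers (0 rose, 0 fell, 19 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 4.95e-08, adjusted p = 0.510 with an estimated correlation) and cholesterol synthesis genes (0 rose, 0 fell, 26 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 5.51e-05, adjusted p = 0.624 with an estimated correlation). Without pFUS 7 and lean control 15, far from their groups, the count was 89 (n = 4 and 5). With 1 library fewer, liver gave 12 (pFUS 10), 25 (pFUS 9), 27 (pFUS 6 or pFUS 8), 31 (control 2), 80 (control 5). In liver the threshold was missed without 1 library by Per3 (7 of 10, 0.116 without pFUS 10), Atf3 (1 of 10, 0.0583 without pFUS 10), Ciart (1 of 10, 0.0583 without pFUS 10), Irs2 (7 of 10, 0.118 without pFUS 8). Adjusted p ran from 9.04e-04 to 0.0322 for the genes named.

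In muscle of obese rats 15 of 12577 genes passed with pFUS (n = 5 and 5), 5 higher and 10 lower. The clock gene Per2 (ENSRNOG00000020254, 1.72 ± 0.27) rose and Arntl (-1.94 ± 0.34) fell, in a list that tested upward (2 rose, 1 fell, 16 did not, 6 and 4 adjusted over the list alone, up, adjusted p = 0.0211, adjusted p = 0.494 with an estimated correlation). The glucocorticoid-induced kinase Sgk1 (ENSRNOG00000011815, 1.36 ± 0.26) rose. Slow fibre genes tested downward (0 rose, 0 fell, 13 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 0.0347, adjusted p = 0.780 with an estimated correlation). Muscle gave, without 1 library, 3 (pFUS 10), 5 (pFUS 7 or pFUS 8), 6 (pFUS 6), 8 (control 2), 35 (control 5). Muscle genes losing the threshold without 1 library were Per2 (1 of 10, 0.0621 without pFUS 10), Sgk1 (8 of 10, 0.180 without pFUS 7), Arntl (7 of 10, 0.118 without pFUS 7). The genes named had adjusted p from 0.0123 to 0.0490.

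In kidney of obese rats 14 of 13359 genes passed (n = 5 and 5), all lower with pFUS: the clock activators Arntl (-2.32 ± 0.24) and Npas2 (-1.72 ± 0.19), the stress factors Atf3 (-3.81 ± 0.58) and Gdf15 (-2.57 ± 0.31), the protease Adamts4 (ENSRNOG00000003538, -3.62 ± 0.54) and Pdk4 (-3.18 ± 0.52) among them. Kidney injury genes tested downward (0 rose, 1 fell, 21 did not, 0 and 2 adjusted over the list alone, down, adjusted p = 7.18e-06, adjusted p = 0.624 with an estimated correlation), as did macrophage markers (0 rose, 0 fell, 15 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 1.87e-06, adjusted p = 0.624 with an estimated correlation). The tubule injury marker Havcr1 was at 996 CPM in control 2, which lay far from its group, and without it the count was 19 (n = 5 and 4). Dropping 1 library gave kidney counts of 5 (pFUS 6 or pFUS 10), 7 (pFUS 9), 8 (pFUS 7), 9 (pFUS 8). In kidney the threshold was missed without 1 library by Atf3 (5 of 10, 0.144 without pFUS 9), Adamts4 (7 of 10, 0.130 without pFUS 9), Pdk4 (8 of 10, 0.226 without pFUS 6). For the genes named, adjusted p ran from 0.00316 to 0.0491.

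In pancreas of obese rats 6 of 9743 genes passed (n = 5 and 5), 5 higher and 1 lower with pFUS. The clock genes Per3 (2.23 ± 0.26), Bhlhe40 (ENSRNOG00000007152, 1.66 ± 0.23), Per2 (1.52 ± 0.18) and Nr1d2 (ENSRNOG00000046912, 1.26 ± 0.17) rose, in a list that tested upward (4 rose, 0 fell, 12 did not, 8 and 4 adjusted over the list alone, up, adjusted p = 0.0106, adjusted p = 0.494 with an estimated correlation), and Ypel2 (ENSRNOG00000005447, -1.02 ± 0.16) fell. Without pFUS 8, of lowest depth and far from its group, the count was 9 (n = 4 and 5). Without 1 library, the pancreas count was 3 (control 1), 11 (control 5). Pancreas genes losing the threshold without 1 library were Bhlhe40 (2 of 10, 0.0607 without control 1), Ypel2 (3 of 10, 0.0709 without control 1). In intestine 9 of 14709 genes passed (n = 5 and 5), 6 higher and 3 lower. Sgk1 (2.51 ± 0.37), Gadd45a (ENSRNOG00000005615, 0.92 ± 0.16) and Mospd3 (ENSRNOG00000001396, 0.86 ± 0.14) rose and Gramd1a (ENSRNOG00000021106, -0.81 ± 0.15), Uhrf2 (ENSRNOG00000011308, -0.71 ± 0.11) and Tp53bp1 (ENSRNOG00000013837, -0.67 ± 0.11) fell. Cholesterol synthesis genes tested upward (0 rose, 0 fell, 26 did not, 18 and 1 adjusted over the list alone, up, adjusted p = 1.92e-10, adjusted p = 0.494 with an estimated correlation), as did pancreatic enzyme genes (0 rose, 0 fell, 6 did not, 4 and 0 adjusted over the list alone, up, adjusted p = 0.0347, adjusted p = 0.729 with an estimated correlation). Cpa1, a pancreatic carboxypeptidase, was at 2321 CPM in pFUS 7 and at most at 0.0673 CPM in the other 9. Without pFUS 7 edgeR called 0 intestine genes (n = 4 and 5, 2092 at an unadjusted p under 0.05). Without obese control 1 and lean controls 11 and 14, which held Fabp6, the count was 376 (n = 5 and 4). The intestine count without 1 library was 0 (control 2, pFUS 7 or pFUS 9), 1 (control 3), 5 (pFUS 8), 14 (pFUS 6), 17 (pFUS 10), 24 (control 5), 27 (control 1), 77 (control 4). In intestine the threshold was missed without 1 library by Sgk1 (4 of 10, 0.0956 without pFUS 9), Gadd45a (6 of 10, 0.149 without pFUS 9), Mospd3 (4 of 10, 0.0956 without pFUS 9), Gramd1a (6 of 10, 0.149 without pFUS 9), Uhrf2 (4 of 10, 0.0956 without pFUS 9), Tp53bp1 (5 of 10, 0.0956 without pFUS 9). Over the genes named, adjusted p ran from 0.00258 to 0.0463.

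In 3 other tissues of obese rats edgeR called none: 0 of 14791 genes in brain (336 at an unadjusted p under 0.05, 8 with DESeq2), 0 of 9400 genes in blood (868 at an unadjusted p under 0.05, 4 with DESeq2) and 0 of 13736 genes in adipose (651 at an unadjusted p under 0.05, 115 with DESeq2). Red cell genes in blood tested downward (0 rose, 0 fell, 21 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 5.31e-05, adjusted p = 0.729 with an estimated correlation). Fast fibre genes in adipose tissue tested upward (0 rose, 0 fell, 14 did not, 13 and 0 adjusted over the list alone, up, adjusted p = 1.02e-06, adjusted p = 0.624 with an estimated correlation), with pFUS 6 and 9 holding muscle genes. Without libraries holding muscle or kidney genes the adipose count was 0 (n = 2 and 4), and without brown fat ones too 1097 (n = 2 and 2). Leaving 1 library out, adipose gave 3 (pFUS 9). Refits of brain lacking 1 library called 2 (control 5). With 1 library fewer, blood gave 1 (control 2), 2 (control 1). Without lean control 12 and lean pFUS 18, far from their groups, blood gave 1.

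**Figure D3:**
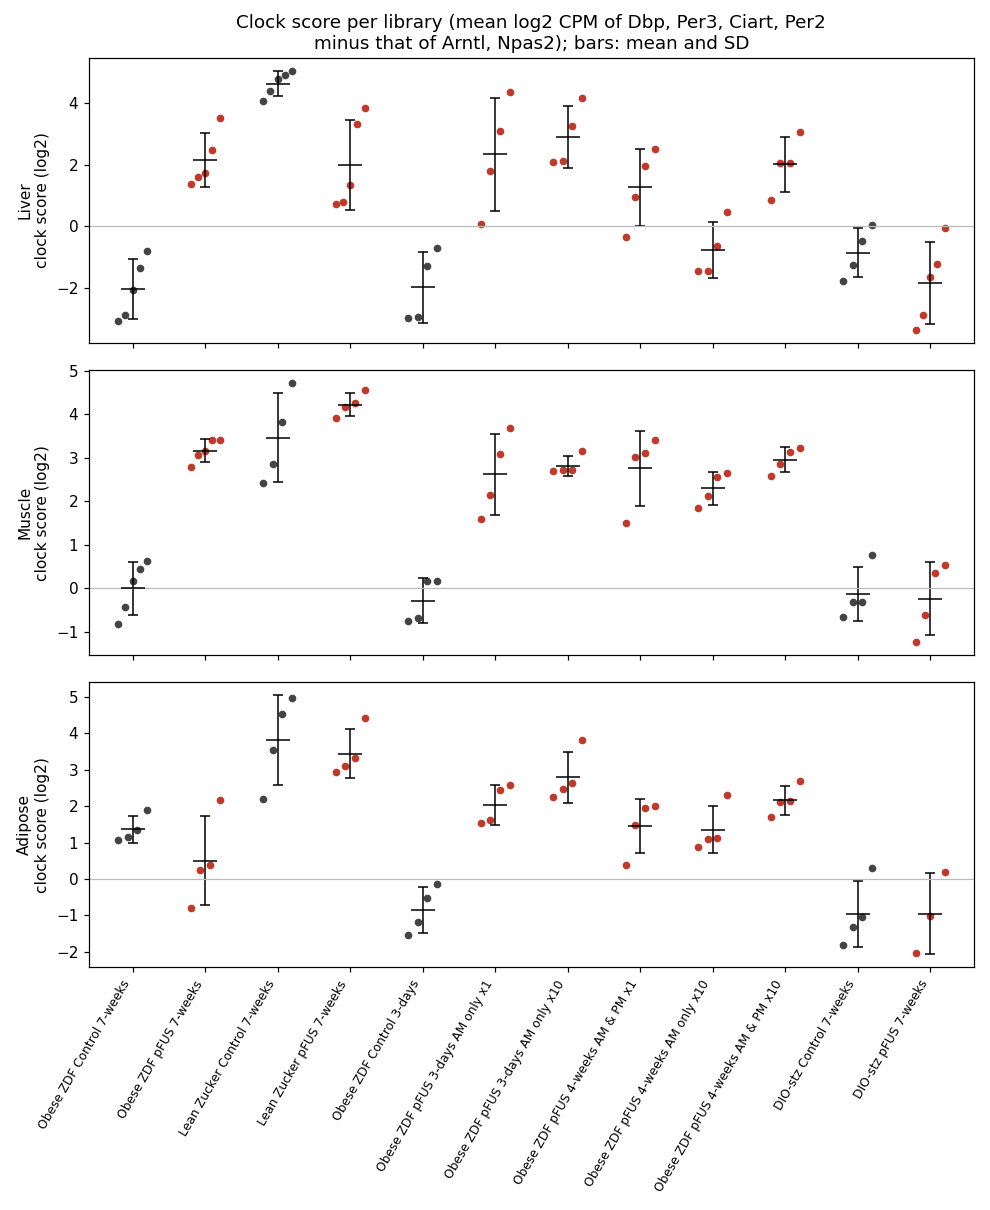
Clock score in liver, muscle and adipose tissue, 1 point per library, controls dark grey and pFUS red, with group mean and SD, adipose libraries holding muscle or kidney genes too. In obese liver at 7 weeks it was -2.04 ± 0.98 in controls and 2.15 ± 0.88 with pFUS, and in lean liver 4.64 ± 0.40 and 2.00 ± 1.47.

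A clock score, chosen after the values were seen, is the mean log2 CPM of Dbp, Per3, Ciart and Per2 minus that of Arntl and Npas2. With pFUS the score of obese 7-week rats differed by 4.18 in liver, 3.17 in muscle, 3.24 in kidney, 2.94 in pancreas and 0.36 in blood, higher in 5 of 5 treated rats than in any control. It differed by 1.99 in intestine, 0.36 in brain and -0.87 in adipose tissue, or -1.06 there without pFUS 6 and 9, which held muscle genes (n = 2 and 4). In lean rats the difference was -2.64 in liver, 0.77 in muscle, 1.28 in intestine, -0.01 in brain and -0.03 in blood, and in adipose tissue each pFUS library held muscle or kidney genes. In DIO-stz rats it ran from -0.98 in liver to 1.19 in intestine over 8 tissues. No p is given for these differences, because the genes of the score were chosen among those that had moved. The labels give no time of day for tissue collection.

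In lean rats with pFUS, 49 of 12585 liver genes passed (n = 5 and 5), 13 higher and 36 lower. The clock activators Arntl (2.61 ± 0.43) and Npas2 (1.78 ± 0.39) rose, in a list that did not pass (2 rose, 0 fell, 16 did not, 2 and 4 adjusted over the list alone, down, adjusted p = 0.223, adjusted p = 0.638 with an estimated correlation). Cldn1 (ENSRNOG00000001926, 1.32 ± 0.27) and Atp2b2 (ENSRNOG00000030269, 1.31 ± 0.28) rose too, for a tight junction protein and a calcium pump. Ppp1r12b (ENSRNOG00000051440, -1.64 ± 0.26) and Ptprb (ENSRNOG00000055293, -1.51 ± 0.28), for phosphatase proteins, fell. Mitochondrial transcripts took 18.3% and 19.0% of counts in pFUS 17 and 19 and 7.74% to 12.7% in controls. In a fit of these 2 groups alone edgeR called 0 genes (1557 at an unadjusted p under 0.05, and 1051 with DESeq2 in the full design), and without control 15 and obese pFUS 7, far from their groups, 5132 (n = 5 and 4). Liver gave, without 1 library, 0 (control 13, control 14, pFUS 17 or pFUS 18), 2 (control 11), 5 (control 12 or pFUS 16), 295 (pFUS 19), 736 (pFUS 20), 4921 (control 15). Liver genes losing the threshold without 1 library were Cldn1 (7 of 10, 0.126 without control 14), Atp2b2 (7 of 10, 0.145 without pFUS 17), Ppp1r12b (4 of 10, 0.0733 without pFUS 18), Ptprb (7 of 10, 0.119 without control 13), Arntl (6 of 10, 0.101 without control 13), Npas2 (7 of 10, 0.145 without pFUS 17). Adjusted p for the genes named ran from 0.0144 to 0.0485.

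In lean intestine 1 of 14709 genes passed (n = 3 and 5), Aloxe3 (ENSRNOG00000007454, 1.79 ± 0.23, adjusted p = 0.00619), a lipoxygenase relative chosen after its values were seen. In a fit of these 2 groups alone edgeR called 0 (1138 at an unadjusted p under 0.05, and 19 with DESeq2 in the full design), and without the 3 controls holding Fabp6 0 (n = 3 and 3, 1026 at an unadjusted p under 0.05). Enterocyte genes tested upward (0 rose, 0 fell, 25 did not, 1 and 0 adjusted over the list alone, up, adjusted p = 2.87e-11, adjusted p = 0.539 with an estimated correlation) and goblet and Paneth genes downward (0 rose, 0 fell, 13 did not, 0 and 5 adjusted over the list alone, down, adjusted p = 0.00395, adjusted p = 0.638 with an estimated correlation), with 2 of 5 controls (11 and 14) and 0 of 3 pFUS libraries holding Fabp6 (at most 1.15 CPM with pFUS). Dropping 1 library gave intestine counts of 0 (pFUS 16), 2 (pFUS 18), 211 (control 15). In intestine the threshold was missed without 1 library by Aloxe3 (1 of 8, 0.118 without pFUS 16). EdgeR called 0 of 12577 genes in muscle (734 at an unadjusted p under 0.05, 48 with DESeq2), 0 of 13736 genes in adipose (1515 at an unadjusted p under 0.05, 8 with DESeq2), 0 of 14791 genes in brain (1020 at an unadjusted p under 0.05, 3 with DESeq2) and 0 of 9400 genes in blood (319 at an unadjusted p under 0.05, 2 with DESeq2). Slow fibre genes in muscle tested upward (0 rose, 0 fell, 13 did not, 12 and 0 adjusted over the list alone, up, adjusted p = 1.49e-04, adjusted p = 0.638 with an estimated correlation), with mitochondrial transcripts at 4.46% to 10.8% of counts in controls and 9.05% to 17.3% with pFUS. In adipose tissue adipocyte genes tested downward (0 rose, 0 fell, 19 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 1.31e-06, adjusted p = 0.638 with an estimated correlation), with 3 of 4 pFUS libraries holding muscle genes. Without 1 library, the adipose count was 1886 (pFUS 16). The muscle count without 1 library was 33 (pFUS 18), 37 (pFUS 19). Adjusted p was 0.00619 for this gene.

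The response to pFUS differed between obese and lean rats, by the interaction test, at 51 of 12585 liver genes, 20 changing more upward in obese rats and 31 more downward. Ciart (5.06 ± 0.86) and Zfp354a (ENSRNOG00000003634, 4.95 ± 0.91), a clock repressor and a zinc finger gene, were among the former and Arntl (-5.18 ± 0.57) and Rprm (ENSRNOG00000005109, -4.90 ± 0.92), a clock activator and a mediator of cell-cycle arrest, among the latter. In intestine 1 of 14709 passed, Aloxe3 (-2.55 ± 0.31, adjusted p = 0.00323), chosen after its values were seen, and 0 without the 3 controls holding Fabp6 (1829 at an unadjusted p under 0.05). EdgeR called 0 of 12577 genes in muscle, 0 of 13736 in adipose, 0 of 14791 in brain and 0 of 9400 in blood. In that order 541, 418, 819 and 357 had an unadjusted p under 0.05, and DESeq2 called 13, 28, 4 and 1. For adipose this is no test of fat, as each lean pFUS library held muscle or kidney genes. Without lean control 15 and obese pFUS 7 the liver count was 3460. Leaving 1 library out, liver gave 32 (obese pFUS 6 or obese pFUS 10), 33 (lean control 13 or lean control 14), 80 (obese control 5), 96 (lean pFUS 20), 104 (obese pFUS 7), 2684 (lean control 15). Refits of intestine lacking 1 library called 2 (obese pFUS 6 or lean pFUS 18). With 1 library fewer, adipose gave 2 (obese pFUS 9). Muscle gave, without 1 library, 2 (obese control 4). Adjusted p ran from 6.49e-05 to 0.0127 for the genes named. Overlap between groups was present for Rprm.

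In obese rats treated for 3 days in the morning, schedules labelled x1 and x10 were each compared with control (n = 4 and 4), and the labels do not say what the multiple counts. In liver x1 gave 70 of 11809 genes, 39 higher and 31 lower. Fkbp5 (ENSRNOG00000022523, 1.52 ± 0.18) and Gpatch4 (ENSRNOG00000018969, 1.70 ± 0.29) rose, the former a co-chaperone induced by glucocorticoids, and Rprm (-2.02 ± 0.33) and Rnf125 (ENSRNOG00000057832, -1.95 ± 0.34) fell. Cpt1a (ENSRNOG00000014254, 0.88 ± 0.19) and Ppara (ENSRNOG00000021463, 0.81 ± 0.16) rose, for mitochondrial fatty acid entry and its controlling receptor, and Gpam (-1.20 ± 0.18) fell. Macrophage markers tested downward (0 rose, 0 fell, 18 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 0.0394, adjusted p = 0.948 with an estimated correlation). Non-polyadenylated RNAs took 4.58% to 5.21% of counts in control liver and 5.87% to 7.46% with x1, 1.96% to 2.63% and 3.01% to 3.71% in muscle, and without them the counts were 68 and 1. Mitochondrial transcripts took 9.22% to 9.89% in control liver and 10.4% to 12.5% with x1. In adipose tissue the clock activator Npas2 (-1.73 ± 0.20) was the 1 gene of 13368 to pass, and in muscle Npas2 (-2.33 ± 0.27) the 1 of 12259, lower with x1 in both. Without x10 adipose 37, which held brown fat genes and shares the fit, the adipose count was 10 (n = 4 and 4). Dropping 1 library gave liver counts of 17 (control 43), 26 (pFUS 33), 28 (pFUS 36), 37 (pFUS 34), 41 (control 41). Without 1 library, the adipose count was 0 (pFUS 33, pFUS 34, pFUS 36 or control 43), 2 (control 41), 3 (control 44). The muscle count without 1 library was 2 (pFUS 35), 5 (pFUS 34), 6 (control 42). Liver genes losing the threshold without 1 library were Gpatch4 (1 of 8, 0.0568 without control 43), Rprm (1 of 8, 0.0514 without control 43), Rnf125 (7 of 8, 0.116 without pFUS 36), Cpt1a (6 of 8, 0.131 without control 43), Ppara (6 of 8, 0.0986 without pFUS 33). In adipose the threshold was missed without 1 library by Npas2 (4 of 8, 0.0869 without control 43). The genes named had adjusted p from 0.00119 to 0.0474. Libraries of the groups overlapped for Ppara.

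With x10, 140 of 11809 liver genes passed, 54 higher and 86 lower. The clock genes Ciart (4.33 ± 0.97) and Per3 (2.94 ± 0.55) rose and Arntl (-3.25 ± 0.64) fell, in a list that did not pass (4 rose, 3 fell, 11 did not, 7 and 5 adjusted over the list alone, up, adjusted p = 0.108, adjusted p = 0.774 with an estimated correlation). Hsd17b2 (ENSRNOG00000013982, 2.53 ± 0.47), an oestradiol-oxidising enzyme, rose, as did Cpt1a (0.84 ± 0.19) and Gys2 (ENSRNOG00000059753, 0.59 ± 0.13), the last glycogen synthase. Chka (ENSRNOG00000016791, -2.47 ± 0.47), Gpam (-1.28 ± 0.18), Angptl4 (-1.46 ± 0.26) and Gckr (ENSRNOG00000048874, -0.97 ± 0.19) fell, the first choline kinase and the last the regulator of glucokinase, and lipogenesis genes tested downward (0 rose, 1 fell, 20 did not, 0 and 1 adjusted over the list alone, down, adjusted p = 0.00406, adjusted p = 0.774 with an estimated correlation). In muscle 186 of 12259 genes passed, 82 higher and 104 lower, with Ciart (2.84 ± 0.49) and Per2 (1.42 ± 0.21) upward and Npas2 (-2.44 ± 0.27) and Auts2 (ENSRNOG00000000885, -1.88 ± 0.32) downward. Non-polyadenylated RNAs took 1.96% to 2.63% of counts in control muscle and 3.89% to 6.61% with x10, and without them the count was 121. Leaving 1 library out, liver gave 34 (pFUS 38), 47 (pFUS 40), 51 (pFUS 37), 55 (control 43), 80 (control 44), 84 (control 41), 92 (control 42). Refits of muscle lacking 1 library called 2 (control 44), 12 (control 43), 20 (pFUS 37), 22 (pFUS 39), 23 (control 41), 55 (pFUS 40), 106 (control 42), 527 (pFUS 38). Liver genes losing the threshold without 1 library were Per3 (8 of 8, 0.118 without pFUS 38), Hsd17b2 (8 of 8, 0.118 without pFUS 38), Arntl (8 of 8, 0.139 without pFUS 37), Chka (7 of 8, 0.130 without pFUS 38), Angptl4 (3 of 8, 0.0876 without pFUS 38), Ciart (7 of 8, 0.162 without control 43), Cpt1a (6 of 8, 0.131 without pFUS 37), Gckr (6 of 8, 0.103 without pFUS 38), Gys2 (8 of 8, 0.0945 without pFUS 37). In muscle the threshold was missed without 1 library by Ciart (5 of 8, 0.0858 without control 43), Per2 (2 of 8, 0.0668 without control 44), Auts2 (4 of 8, 0.0804 without pFUS 39). For the genes named, adjusted p ran from 0.00206 to 0.0491.

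In adipose tissue 3 of 13368 genes passed with x10: Dbp (2.55 ± 0.32) rose and Npas2 (-2.42 ± 0.21) and Arntl (-2.08 ± 0.29) fell, in a list that tested upward (1 rose, 2 fell, 16 did not, 14 and 4 adjusted over the list alone, up, adjusted p = 8.31e-05, adjusted p = 0.288 with an estimated correlation). Without x10 adipose 37, with 106 CPM of Ucp1, the count was 5 (n = 3 and 4). With 1 library fewer, adipose gave 1 (pFUS 39, pFUS 40, control 42 or control 43), 5 (pFUS 37), 8 (control 41). Adipose genes losing the threshold without 1 library were Dbp (4 of 8, 0.164 without control 43), Arntl (7 of 8, 0.172 without pFUS 40). The clock score differed by 4.32 with x1 and 4.90 with x10 in liver, 2.91 and 3.10 in muscle and 2.88 and 3.64 in adipose tissue, higher in 4 of 4 treated rats than in any control. Between x10 and x1, 55 of 11809 liver genes differed, 15 higher and 40 lower with x10: C4a (ENSRNOG00000047657, 1.17 ± 0.23) and Lpar3 (ENSRNOG00000015260, 1.08 ± 0.19) were higher, a complement gene with a near-identical copy and a lipid receptor, and Bach2 (ENSRNOG00000006170, -1.93 ± 0.28) and Gpatch4 (-1.71 ± 0.29) lower. Non-polyadenylated RNAs took 3.93% to 6.14% of counts in liver with x10, and without them the count was 59. EdgeR called 0 of 13368 genes in adipose (1480 at an unadjusted p under 0.05, 32 with DESeq2) and 0 of 12259 genes in muscle (1061 at an unadjusted p under 0.05, 62 with DESeq2). Liver gave, without 1 library, 4 (x1 35), 11 (x1 33 or x10 37), 14 (x10 38), 15 (x10 40), 20 (x1 36), 22 (x10 39), 143 (x1 34). Dropping 1 library gave muscle counts of 1 (x10 39), 15 (x10 40). In liver the threshold was missed without 1 library by C4a (6 of 8, 0.154 without x1 36), Lpar3 (5 of 8, 0.103 without x1 33), Gpatch4 (5 of 8, 0.0680 without x1 33). Over the genes named, adjusted p ran from 4.34e-04 to 0.0491.

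After 4 weeks 3 schedules without a control group were compared in obese rats (n = 4 each). Treatment morning and evening (AM-PM) at x10 differed from AM only x10 at 151 of 12036 liver genes, 68 higher and 83 lower. Non-polyadenylated RNAs took 7.06% to 8.40% of counts with AM-PM and 4.29% to 7.34% with AM only, and without them the count was 155. Dbp (2.11 ± 0.38) and Slc1a2 (ENSRNOG00000005479, 1.79 ± 0.39) were higher, a clock output factor and a glutamate transporter, and Chka (-1.69 ± 0.33) and Slc34a2 (ENSRNOG00000004626, -1.68 ± 0.31) lower, choline kinase and a phosphate transporter. EdgeR called 0 of 13669 genes in adipose (825 at an unadjusted p under 0.05, 14 with DESeq2) and 0 of 12199 genes in muscle (456 at an unadjusted p under 0.05, 3 with DESeq2). Without 1 library, the liver count was 4 (AM-PM 30), 17 (AM-PM 31), 25 (AM only 26), 33 (AM-PM 32), 50 (AM only 25), 93 (AM only 27). The adipose count without 1 library was 2 (AM only 27). Liver genes losing the threshold without 1 library were Dbp (6 of 8, 0.120 without AM only 26), Slc1a2 (7 of 8, 0.148 without AM only 26), Chka (8 of 8, 0.141 without AM only 26), Slc34a2 (6 of 8, 0.115 without AM-PM 30). Adjusted p for the genes named ran from 0.0365 to 0.0478.

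AM-PM x10 differed from AM-PM x1 at 100 of 12036 liver genes, 29 higher and 71 lower. Nqo1 (ENSRNOG00000012772, 1.37 ± 0.25) and Jund (ENSRNOG00000019568, 0.87 ± 0.17) were higher, a quinone reductase and a component of AP-1, and Col27a1 (ENSRNOG00000007657, -1.57 ± 0.27) and Rasd1 (ENSRNOG00000003348, -1.30 ± 0.25) lower, a collagen and a Ras-like protein. EdgeR called 0 of 13669 genes in adipose (589 at an unadjusted p under 0.05, 1 with DESeq2) and 0 of 12199 genes in muscle (1220 at an unadjusted p under 0.05, 15 with DESeq2). Leaving 1 library out, liver gave 0 (x1 23), 1 (x1 22), 4 (x1 24 or x10 32), 15 (x10 29), 31 (x1 21). In liver the threshold was missed without 1 library by Nqo1 (5 of 8, 0.129 without x1 22), Jund (6 of 8, 0.129 without x1 22), Col27a1 (6 of 8, 0.115 without x10 32), Rasd1 (5 of 8, 0.117 without x1 22). Adjusted p ran from 0.0321 to 0.0439 for the genes named.

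In DIO-stz rats the groups differed in sex and the fit held a term for it. In liver 148 of 12870 genes passed with pFUS (n = 5 and 4), 46 higher and 102 lower. Mitochondrial transcripts took 8.52% to 13.9% of counts in controls and 4.82% to 8.48% with pFUS. Lipogenesis genes tested upward (7 rose, 0 fell, 14 did not, 14 and 0 adjusted over the list alone, up, adjusted p = 3.06e-19, adjusted p = 0.116 with an estimated correlation), with Pnpla3 (11.51 ± 1.16, 239 ± 314 against 0.144 ± 0.0353 CPM), Scd (7.70 ± 1.21), Fasn (ENSRNOG00000045636, 4.64 ± 0.64) and Acly (ENSRNOG00000016924, 3.62 ± 0.49), for a lipid droplet protein, a desaturase, fatty acid synthase and ATP citrate lyase. Cholesterol synthesis genes tested upward (1 rose, 0 fell, 25 did not, 11 and 0 adjusted over the list alone, up, adjusted p = 3.05e-13, adjusted p = 0.165 with an estimated correlation), with Sqle (ENSRNOG00000009550, 2.02 ± 0.42). Fatty acid oxidation genes tested downward (1 rose, 8 fell, 21 did not, 2 and 16 adjusted over the list alone, down, adjusted p = 2.64e-15, adjusted p = 0.0889 with an estimated correlation), with Acot1 (ENSRNOG00000055221, -6.78 ± 0.65) and Eci1 (ENSRNOG00000008843, -2.11 ± 0.23), and so did bile acid genes (0 rose, 3 fell, 16 did not, 0 and 5 adjusted over the list alone, down, adjusted p = 2.43e-06, adjusted p = 0.0889 with an estimated correlation), with Nr0b2 (ENSRNOG00000007229, -2.17 ± 0.30) and Cyp8b1 (ENSRNOG00000019481, -1.44 ± 0.18). Acot1 has close copies among which reads may be split. Pklr (ENSRNOG00000020420, 2.25 ± 0.38) and Bhlhe40 (2.66 ± 0.28) rose, for liver pyruvate kinase and a clock gene. With males only the count was 6 (n = 4 and 2). Refits of liver lacking 1 library called 61 (pFUS 11), 62 (control 6), 82 (control 4), 87 (control 3). Liver genes losing the threshold without 1 library were Acly (1 of 9, 0.0740 without pFUS 11), Fasn (1 of 9, 0.0877 without pFUS 11), Pklr (4 of 9, 0.111 without pFUS 11), Scd (1 of 9, 0.0575 without control 5), Sqle (8 of 9, 0.250 without pFUS 11). The genes named had adjusted p from 1.43e-04 to 0.0467. The groups overlapped for Sqle.

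In pancreas of DIO-stz rats 118 of 11790 genes passed (n = 4 and 4), 45 higher and 73 lower with pFUS. The insulin gene Ins2 (ENSRNOG00000020405, 3.12 ± 0.53) rose in the islet list (1 rose, 0 fell, 23 did not, 2 and 0 adjusted over the list alone, up, adjusted p = 0.0194, adjusted p = 0.801 with an estimated correlation). Amy1a (ENSRNOG00000033529, 5.74 ± 0.45) and Tff2 (ENSRNOG00000001162, 5.10 ± 0.88) rose too, for amylase and a trefoil peptide. The trypsinogens Prss3 (ENSRNOG00000031385, -7.67 ± 0.86) and Prss2 (ENSRNOG00000032916, -2.14 ± 0.37) fell, and like amylase have near-identical copies. Non-polyadenylated RNAs took 85.8% of counts in control 6 and 25.0% to 34.0% in the other controls, against 16.4% to 19.9% with pFUS. Without these RNAs the count was 128, and without control 6 64 (n = 4 and 3). With males only it was 11 (n = 3 and 2). With 1 library fewer, pancreas gave 19 (pFUS 11), 64 (control 6), 68 (pFUS 7), 345 (control 5). In pancreas the threshold was missed without 1 library by Tff2 (6 of 8, 0.144 without control 6), Ins2 (6 of 8, 0.272 without pFUS 11), Prss2 (4 of 8, 0.0759 without pFUS 11). For the genes named, adjusted p ran from 1.14e-04 to 0.0466. Overlap between groups was present for Prss2.

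In kidney of DIO-stz rats 23 of 14481 genes passed (n = 5 and 4), 14 higher and 9 lower. Mitochondrial transcripts took 28.9% to 49.2% of counts in controls and 5.95% to 31.8% with pFUS. Anxa13 (ENSRNOG00000007980, 4.90 ± 0.84), an annexin, rose, and Atp12a (ENSRNOG00000020685, -3.68 ± 0.46) and Creb3l3 (ENSRNOG00000032202, -3.36 ± 0.49) fell, a proton pump and a transcription factor. Cyp2b2 was called too, but its counts came from females, 1865 in pFUS 11 alone and 38 in 2 controls, so no change is reported for it. With males only edgeR called 0 (n = 4 and 2, 3194 at an unadjusted p under 0.05). Kidney gave, without 1 library, 0 (control 3, pFUS 7, pFUS 10 or pFUS 11), 13 (pFUS 9), 131 (control 4), 379 (control 6). Kidney genes losing the threshold without 1 library were Anxa13 (6 of 9, 0.172 without control 5), Atp12a (4 of 9, 0.0810 without control 3), Creb3l3 (5 of 9, 0.0945 without pFUS 10). Over the genes named, adjusted p ran from 0.0255 to 0.0488. Libraries of the groups overlapped for Anxa13.

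In DIO-stz adipose 7 of 15085 genes passed (n = 3 and 4), the sex term leaving 3 pFUS males against 2 male controls. Cish (ENSRNOG00000029543, 3.07 ± 0.26) and Clcn4 (ENSRNOG00000003533, 2.89 ± 0.32) were among 4 that rose, a suppressor of cytokine signalling and a chloride transporter. Grhl3 (ENSRNOG00000029427, -3.18 ± 0.35) and Masp1 (ENSRNOG00000001827, -2.05 ± 0.19) were among 3 that fell, a transcription factor and a complement protease. Without pFUS 9, with 1320.0 CPM of Cpa1, the count was 5 (n = 2 and 4). Leaving 1 library out gave 0 (control 3, 4 or 5), 1 (control 6), 2 (pFUS 8). Genes lost without 1 library were Cish (4 of 7, 0.186 without control 6), Clcn4 (7 of 7, 0.241 without control 6), Grhl3 (6 of 7, 0.241 without control 6), Masp1 (6 of 7, 0.186 without control 6). In blood 3 of 10846 genes passed (n = 5 and 4), all lower with pFUS: Cpt1a (-0.87 ± 0.11) and, chosen after their values were seen, the ferritin-like Fthl17e (ENSRNOG00000003783, -5.20 ± 0.66, adjusted p = 0.00541) and the receptor gene Flt4 (ENSRNOG00000002511, -4.98 ± 0.68, adjusted p = 0.00735). Neutrophil genes tested downward (0 rose, 0 fell, 14 did not, 0 and 3 adjusted over the list alone, down, adjusted p = 1.96e-09, adjusted p = 0.295 with an estimated correlation). Without 1 library, the blood count was 0 (pFUS 8, pFUS 10 or pFUS 11), 1 (pFUS 7), 6 (control 5). Blood genes losing the threshold without 1 library were Cpt1a (8 of 9, 0.141 without pFUS 7), Flt4 (5 of 9, 0.0981 without pFUS 10), Fthl17e (3 of 9, 0.0709 without pFUS 11). Adjusted p for the genes named ran from 0.00541 to 0.0456.

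EdgeR called 0 of 12640 genes in muscle (921 at an unadjusted p under 0.05, 161 with DESeq2), 0 of 14833 genes in intestine (567 at an unadjusted p under 0.05, 15 with DESeq2) and 0 of 15301 genes in brain (253 at an unadjusted p under 0.05, 2 with DESeq2) in DIO-stz rats. In muscle adipocyte genes tested downward (0 rose, 0 fell, 17 did not, 1 and 10 adjusted over the list alone, down, adjusted p = 1.76e-08, adjusted p = 0.143 with an estimated correlation), and in brain hypothalamic peptide genes did (0 rose, 0 fell, 33 did not, 0 and 0 adjusted over the list alone, down, adjusted p = 6.21e-04, adjusted p = 0.598 with an estimated correlation). The muscle count without 1 library was 1 (control 4). Diet resistant (2 females) against DIO-stz rats, both with pFUS, gave 0 of 12870 genes in liver (270 at an unadjusted p under 0.05, 8 with DESeq2) and 0 of 11790 genes in pancreas (264 at an unadjusted p under 0.05, 24 with DESeq2). Leaving 1 library out, liver gave 1 (DIO-stz 10 or DIO-stz 11). Refits of pancreas lacking 1 library called 1 (resistant 1).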

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

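Of the tests in this part, those of the 3 patterns weighed were chosen only after the result was seen, except that of obesity as the cause of most other muscle genes, and so was the count of splits for 4-week AM-PM x10 against AM only x10 in adipose tissue.

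Clock genes differed between pFUS and control rats in several tissues. Liver and muscle clock scores of the same control animals, each minus its group mean over 4 groups and permuted within groups, had r = 0.655 (n = 17, permutation p = 0.00384, rho = 0.689 with permutation p = 0.00147, r = 0.614 without the 2 farthest, adjusted p = 0.0494 over 15 relations), as liver and kidney ones had r = 0.804 (n = 9, adjusted p = 0.0494). The other 13 relations did not pass, among them liver and muscle with pFUS, r = 0.459 (n = 33, permutation p = 0.0593, adjusted p = 0.148), or 0.455 with obese pFUS 8 and 9 exchanged in muscle (permutation p = 0.0583), as 1 gene suggests, and 3 had r below 0, down to -0.357. A phase of day differing between animals stays open, as does an effect in obese ZDF rats alone, since the labels give no collection times. For liver, pFUS moving clock genes the same way in every rat is argued against by the 7 past the threshold in obese liver. Their mean log2 CPM, signed by direction there, differed by -1.04 in lean liver with pFUS (n = 5 and 5, exact p = 0.00794). All 5 treated rats lay below every control. The mean differed by -1.03 without control 15, far from its group (n = 5 and 4, exact p = 0.0317). Without pFUS 16, 17 and 18 too, picked with no rule, it differed by -0.344 (n = 2 and 4, too few for a p under 0.05). A shared phase shift stays open, as control scores were -2.04 in obese and 4.64 in lean liver. Lean muscle and intestine (0.77 and 1.28 in score) stay open. Lean pFUS livers 17 and 19 were high in mitochondrial counts.

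Muscle of obese and lean controls differed at 6610 genes. The lowest share of non-polyadenylated RNAs was 4.02% in lean 7-week muscle and the highest 0.0205% in obese, as libraries of 2 kinds need. That obesity lowered these RNAs is argued against by the lowest share in 3-day and 4-week obese muscle, 1.63%. Of 6529 other genes past the threshold, 88.3% had a mean in obese 3-day controls nearer to lean than to obese 7-week controls. This argues against obesity as the cause of most. Age and cohort differ too and stay open, as does obesity for the rest.

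In 7-week adipose tissue 5 libraries held muscle genes at the level of muscle. Muscle mixed into fat is argued against for them by the highest Adipoq, 15.6 CPM, against 260.8 CPM at the highest in muscle libraries, which leaves muscle libraries under adipose labels as a candidate explanation. No biological explanation was tested.

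Splits calling as many genes were a share under 0.05, unadjusted over counts, for the following, weak evidence against chance. Each has the number of such splits, the real one included, and the highest count of any other. Obese against lean controls gave liver 1798 (1 of 100, 396), muscle 6610 (1 of 100, 6313), brain 50 (1 of 100, 6), blood 297 (2 of 100, 694). Obese rats with pFUS gave liver 50 (1 of 100, 8), intestine 9 (2 of 100, 23), kidney 14 (1 of 100, 7), pancreas 6 (2 of 100, 47). The difference between these 2 effects gave liver 51 (3 of 100, 1261), intestine 1 (4 of 100, 2). 3-day x1 gave liver 70 (1 of 35, 5). 3-day x10 gave liver 140 (1 of 35, 1), adipose 3 (1 of 35, 0), muscle 186 (1 of 35, 1). 3-day x10 against x1 gave liver 55 (1 of 35, 3). 4-week AM-PM x10 against AM only x10 gave liver 151 (1 of 35, 1). 4-week AM-PM x10 against x1 gave liver 100 (1 of 35, 1). DIO-stz rats with pFUS gave liver 148 (2 of 100, 1798), kidney 23 (4 of 100, 3638). Splits at several times the real count point to sample structure, as in obese pancreas, liver of the difference and DIO-stz liver and kidney.

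Chance cannot be excluded for these counts, given in the same way. Obese against lean controls gave adipose 4 (2 of 35, 455), intestine 2 (11 of 100, 902). Obese rats with pFUS gave muscle 15 (10 of 100, 4510). Lean rats with pFUS gave liver 49 (5 of 100, 5518), intestine 1 (4 of 56, 1018). 3-day x1 gave adipose 1 (2 of 35, 1), muscle 1 (5 of 35, 3). DIO-stz rats with pFUS gave adipose 7 (2 of 35, 35), blood 3 (5 of 100, 267), pancreas 118 (2 of 35, 246). Splits at several times the real count occurred in control adipose and intestine, obese muscle, lean liver and intestine and DIO-stz adipose and blood.

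For a real count of 0 every split calls as many, so splits say nothing about chance. Only the highest count of any other is given, with the number of splits. Obese rats with pFUS had adipose 1350 (35), brain 50 (100), blood 8 (100). Lean rats with pFUS had adipose 8387 (35), muscle 14 (35), brain 549 (100), blood 10 (100). The difference between these 2 effects had adipose 3861 (100), muscle 2145 (100), brain 1 (100), blood 1 (100). 3-day x10 against x1 had adipose 1 (35), muscle 205 (35). 4-week AM-PM x10 against AM only x10 had adipose 2671 (35), muscle 1 (35). 4-week AM-PM x10 against x1 had adipose 1 (35), muscle 18 (35). DIO-stz rats with pFUS had muscle 3 (35), intestine 380 (100), brain 100 (100). Splits calling many genes point to a structure of the samples.

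Of 180 Dixon's tests, 1 per group and measure over 3 measures, 26 found a library far from the others, where chance gives about 1 in 20. Each is given with the range of the others in its group. For the clock score they were DIO-stz control kidney 6 2.19 (-0.50 to -0.28), lean control intestine 14 -2.21 (0.28 to 0.97), obese control blood 4 0.51 (0.28 to 0.33), obese control brain 4 0.0612 (-0.45 to -0.35), obese pFUS 3-day AM only x10 muscle 38 3.17 (2.69 to 2.72). For the median correlation with the tissue's libraries they were DIO-stz control adipose 3 0.955 (0.972 to 0.972), DIO-stz control muscle 6 0.970 (0.975 to 0.976), DIO-stz pFUS brain 10 0.960 (0.971 to 0.975), DIO-stz pFUS kidney 11 0.902 (0.959 to 0.968), DIO-stz pFUS liver 7 0.928 (0.952 to 0.956), lean control blood 12 0.939 (0.969 to 0.978), lean control brain 11 0.933 (0.967 to 0.974), lean control liver 15 0.911 (0.967 to 0.972), lean pFUS blood 18 0.933 (0.972 to 0.977), lean pFUS brain 19 0.870 (0.962 to 0.977), obese control kidney 2 0.920 (0.952 to 0.965), obese pFUS 4-week AM-PM x1 muscle 22 0.937 (0.977 to 0.980), obese pFUS adipose 6 0.676 (0.835 to 0.850), obese pFUS liver 7 0.968 (0.977 to 0.980), obese pFUS pancreas 8 0.942 (0.972 to 0.978). For the percentage of non-polyadenylated RNAs they were DIO-stz control intestine 5 0.00503 (0.00322 to 0.00351), DIO-stz control pancreas 6 85.8 (25.0 to 34.0), lean pFUS liver 16 0.0622 (0.00308 to 0.0196), obese control muscle 4 0.0205 (0.00232 to 0.00624), obese pFUS 4-week AM-PM x1 muscle 22 7.26 (3.12 to 3.25), obese pFUS brain 10 0.0279 (0.00556 to 0.00813).

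The effect of pFUS differed between obese and lean rats, by the interaction test, at 51 liver genes and 1 intestine gene, with log2 differences of 5.06 for Ciart, 4.95 for Zfp354a, -5.18 for Arntl and -4.90 for Rprm in liver. The liver count ran from 32 to 2684 with 1 library left out. The intestine gene did not pass without the controls holding Fabp6.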

How the results depend on the processing

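The tests without named kinds of libraries or without non-polyadenylated RNAs were chosen only after the result was seen, and the other alternatives before the data were examined. Libraries far from their group in correlation are those found by Dixon's test. Those picked with no rule are lean control 15 and lean pFUS 16, 17 and 18 in liver, obese control 1, lean control 11 and lean pFUS 19 in brain, and DIO-stz controls 3 and 6 and pFUS 11 in kidney and control 6 in blood. No paired analysis was possible because the groups compared share no replicate numbers.

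Of 754 counts under an alternative 485 stayed within 1.5 times the count reported and 269 moved. RLE factors in place of TMM moved 0 of 51, and leaving out 1 library 172 of 502. Of 2333 pairs of an alternative and a gene named or ranked by the rule, 1796 kept direction and threshold, 537 lost the threshold and 0 turned, and 64 of 162 such genes passed under every alternative run. Cyp2b2 in DIO-stz kidney had no fold without library 11. With an estimated correlation 0 list tests passed in 6 comparisons. Where a count moved, the cause was not tested.

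DESeq2 moved 49 of 51 counts. For obese against lean controls adipose 194, intestine 142, brain 104, blood 505. For obese rats with pFUS liver 135, adipose 115, muscle 49, intestine 571, brain 8, blood 4, kidney 90, pancreas 28. For lean rats with pFUS liver 1051, adipose 8, muscle 48, intestine 19, brain 3, blood 2. For the difference between these 2 effects liver 330, adipose 28, muscle 13, intestine 52, brain 4, blood 1. For 3-day x1 liver 253, adipose 18, muscle 36. For 3-day x10 liver 304, adipose 27, muscle 796. For 3-day x10 against x1 liver 180, adipose 32, muscle 62. For 4-week AM-PM x10 against AM only x10 liver 513, adipose 14, muscle 3. For 4-week AM-PM x10 against x1 liver 446, adipose 1, muscle 15. For DIO-stz rats with pFUS liver 369, adipose 118, muscle 161, intestine 15, brain 2, blood 16, kidney 416, pancreas 326. For diet resistant rats liver 8, pancreas 24.

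With no filter on low counts, these counts moved. For lean rats with pFUS liver 23, muscle 21. For 3-day x1 adipose 5, muscle 3. For 3-day x10 against x1 muscle 2. For DIO-stz rats with pFUS muscle 7, blood 5, kidney 35. For diet resistant rats pancreas 1. With male libraries only, these counts moved. For DIO-stz rats with pFUS liver 6, blood 0, kidney 0, pancreas 11. With no sex term, these counts moved. For DIO-stz rats with pFUS liver 82, adipose 3, kidney 1. With only the 2 groups compared, these counts moved. For obese rats with pFUS muscle 5, intestine 32. For lean rats with pFUS liver 0, muscle 1, intestine 0, brain 1.

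In these fits n is in brackets. Without libraries far from their group in correlation, moved counts were obese against lean controls brain 114 (5 and 4), blood 709 (5 and 4), obese rats with pFUS liver 89 (4 and 5), blood 1 (5 and 5), lean rats with pFUS liver 5132 (5 and 4), the difference between these 2 effects liver 3460, DIO-stz rats with pFUS adipose 0 (3 and 3), kidney 0 (4 and 4). Without libraries picked with no rule, moved counts were obese against lean controls liver 3522 (5 and 4), brain 98 (4 and 4), obese rats with pFUS liver 177 (5 and 5), lean rats with pFUS liver 3323 (2 and 4), the difference between these 2 effects liver 1753, DIO-stz rats with pFUS kidney 5 (4 and 2). Without non-polyadenylated RNAs, moved counts were 3-day x10 muscle 121. Without the libraries holding ileal genes, moved counts were obese against lean controls intestine 0 (4 and 3), obese rats with pFUS intestine 376 (5 and 4), lean rats with pFUS intestine 0 (3 and 3), the difference between these 2 effects intestine 0. Without the libraries holding muscle or kidney genes, moved counts were obese against lean controls adipose 36 (4 and 2). Without the libraries holding muscle, kidney or brown fat genes, moved counts were obese against lean controls adipose 2067 (2 and 2), obese rats with pFUS adipose 1097 (2 and 2). Without the library holding brown fat genes, moved counts were 3-day x1 adipose 10 (4 and 4), 3-day x10 adipose 5 (3 and 4). Without the library holding pancreas genes, moved counts were obese rats with pFUS intestine 0 (4 and 5). Without the library of most non-polyadenylated RNAs, moved counts were DIO-stz rats with pFUS pancreas 64 (4 and 3).

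Leave-one-out counts ranged as follows, and where an arm is left with 1 library it is assumed to vary like the other groups. For obese against lean controls liver 1313 to 2199, adipose 0 to 5, muscle 5754 to 6935, intestine 2 to 187, brain 24 to 54, blood 69 to 569. For obese rats with pFUS liver 12 to 80, adipose 0 to 3, muscle 3 to 35, intestine 0 to 77, brain 0 to 2, blood 0 to 2, kidney 5 to 20, pancreas 3 to 11. For lean rats with pFUS liver 0 to 4921, adipose 0 to 1886, muscle 0 to 37, intestine 0 to 211, brain 0 to 0, blood 0 to 0. For the difference between these 2 effects liver 32 to 2684, adipose 0 to 2, muscle 0 to 2, intestine 1 to 2, brain 0 to 0, blood 0 to 0. For 3-day x1 liver 17 to 81, adipose 0 to 3, muscle 1 to 6. For 3-day x10 liver 34 to 111, adipose 1 to 8, muscle 2 to 527. For 3-day x10 against x1 liver 4 to 143, adipose 0 to 0, muscle 0 to 15. For 4-week AM-PM x10 against AM only x10 liver 4 to 199, adipose 0 to 2, muscle 0 to 0. For 4-week AM-PM x10 against x1 liver 0 to 92, adipose 0 to 0, muscle 0 to 0. For DIO-stz rats with pFUS liver 61 to 187, adipose 0 to 9, muscle 0 to 1, intestine 0 to 0, brain 0 to 0, blood 0 to 6, kidney 0 to 379, pancreas 19 to 345. For diet resistant rats liver 0 to 1, pancreas 0 to 1.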

Other observations

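All values in this part were chosen only after the result was seen, and no tests were run on them.

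Ifit1, which binds foreign RNA as part of the interferon response, ran from 1.60 to 284 CPM in blood and from 0 to 160.3 CPM in intestine of the obese 7-week cohort, control and pFUS together. In lean rats it ran from 0 to 4.32 CPM in blood and from 0 to 0.136 CPM in intestine. In liver it ran from 0 to 12.8 CPM in the obese 7-week cohort, 0 to 0.326 CPM in obese rats at 3 days and 0 to 0.176 CPM in obese rats at 4 weeks. Ubd ran from 0 to 0.171 CPM in obese 7-week liver and 10.2 to 32.2 CPM in lean liver. In obese liver it was 8.75 to 35.0 CPM at 3 days and 8.45 to 52.4 at 4 weeks.

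Fabp6, which binds bile acids in the ileum, was uneven in intestine of DIO-stz rats as well. It was at 6893, 3744 and 401 CPM in controls 3, 4 and 6 and at 1.99 CPM in control 5. With pFUS it was at 5425 CPM in rat 9, 114 CPM in rat 7 and at most 6.62 CPM in rats 8, 10 and 11. The labels do not name the part of the intestine.

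In liver, non-polyadenylated RNAs took at most 0.0622% of counts in 7-week Zucker rats and 3.93% to 8.40% in 3-day and 4-week obese rats. In adipose tissue they took 0.00471% to 0.0361% in DIO-stz rats and 3.63% to 14.7% in 7-week Zucker rats, where the labels give a total RNA kit for both.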
